A study of Arabidopsis thaliana with 3 samples.

How the data were processed

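Total RNA of Arabidopsis thaliana, accession Col-0, was measured on 3 Affymetrix ATH1 arrays. On this array a gene is read by a probe set, a group of short oligonucleotides whose brightness is combined into 1 value. A pair of arrays carried RNA of germinating pollen and 1 array carried RNA of seedlings. Pollen was left for 6 h at 25°C on a medium with 13.5% sucrose, and about 80% of it had germinated, per the labels. Each labelling started from 10 µg of total RNA. The sample label of the seedlings gives a day of 18 h light and 6 h dark, whereas the series' design text gives 16 h and 8 h for the plants, and this was not settled. The design text speaks of a duplicated hybridisation of pollen RNA. Nothing says that the pollen arrays came from separate plants, so p-values measure only the spread between these 2 arrays, which may be technical.

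The deposited values are array intensities on a linear scale, made by the authors with MAS5 (version not given in the sources used here), per the submitters' processing notes. The design text names the programs GCOS 1.2 and Excel 2004. The arrays had the same 2% trimmed mean of 122 in the deposited table, with 2% of the probe sets left out at each end, so each array had already been scaled to a common level. That scaling sets most of the array to the same level whatever the amount of messenger RNA was, and differences are therefore relative to the rest of the same array. The table held no detection calls. The scanner files were not used here. Precision is limited by the number of arrays, since the seedling group has 1 array and the spread has 1 residual degree of freedom.

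Of 22810 probe sets, 64 were array controls and were left out of tests. The platform annotation gave exactly 1 gene for 13513 of the other 22746 (59.4%), several genes for 503, and did not list 8730, which are unnamed here. Of the 13513, 13436 matched a gene of the TAIR10.1 reference table, which was used for names only, and 1580 had a symbol other than the locus. The sources name no genome build, so no coordinates are given. Probe sets with several genes were not named.

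Signals were scaled once more to equal 2% trimmed means, which changed them very little. An offset of 14.7, the 30th percentile of all signals, was added before log2, which understates the differences of dim probe sets. The pooled median signal, 42.3, served as the floor. A probe set was tested if it was above the floor on both pollen arrays or on the seedling array. The test was limma (lmFit and eBayes with a variance trend, two-sided) over all 3 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The single seedling array is assumed to vary like the pollen arrays. A second count used no test. It took probe sets whose signal on each pollen array was above the floor and at least 10 times the higher of the seedling signal and the floor, and the reverse for lower signals. Where a tissue was at or under the floor on all its arrays, a fold is given as at least the bright mean over the floor. The floor lies under the highest control probe set without a target on the pollen arrays (47.1 and 65.7), so bounds for genes dim in pollen hold against the floor and not against that control. Other folds are ratios of mean signals.

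Gene lists were tested with limma's camera with an inter-gene correlation preset at 0.01, adjusted over the lists tested, and again with an estimated correlation. The median of each list was placed among 10000 random lists of the same size matched on mean signal in 10 bins. A second median, with signals under the floor raised to it, was made without the offset and from the arithmetic mean of the pollen signals. The 2 medians thus differ in more than the floor, and the place among random lists belongs to the first. Of 19 lists with 553 members fixed before the data were examined, 78 members had a probe set of their own in the annotation. The lists of sperm cell genes and of cytosolic ribosomal proteins had 0 measured members, and 10 lists with at least 3 tested members were tested; that minimum was set after the annotation was seen. A further 22 gene families were chosen from the symbols in the annotation before their values were read, and the symbol patterns of 2 of them, the CYP71 and IQD families, were corrected after values had been seen. The result of 1 of these families is not reported here.

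The genes named in the text follow a rule also fixed before the data were examined. It takes the 6 largest differences in each direction among called probe sets above the floor on all 3 arrays and at least 2-fold on both pollen arrays. It adds the 8 genes with the highest pollen mean among those called with the seedling at or under the floor, the 8 with the highest seedling signal among those called with both pollen arrays at or under the floor, up to 3 called members of each list in each direction, and all measured reference genes. Other list members and the members of the 22 families were named after their values were seen. For a gene with several probe sets, the one with the highest mean signal stands for it.

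The fit was tested on simulated data for this comparison, with 200 of the 22746 probe sets changed, of which 12212 probe sets passed the filter. It called 28 of 50 probe sets changed 2-fold, 47 of 50 changed 4-fold, 50 of 50 changed 8-fold and 50 of 50 changed 16-fold in the right direction. All changed probe sets were drawn from those with a mean pollen signal above 200, so these counts hold for bright probe sets only. Of the fit's 271 calls, 96 were false (35.4%), and 89 of these were calls of lower signal in pollen. Without the filter it made 210 calls, of which 30 were false. The filter admits a probe set because its single seedling value was high, which favours false calls of lower signal. Every simulated array was drawn from the signals of the pollen arrays, so the different background of the seedling array was not simulated. Another case changed 8000 probe sets of any brightness, with rises and falls equally likely, and left out the scaling step. There 322 of 2813 calls were false (11.4%), and 17 had the wrong direction. The data gave 7972 calls under the scaled fit, so this share may not carry over to them. With no change simulated the fit made 0 calls. The 10-fold rule took 0 unchanged probe sets as higher and 8 of 22546 as lower. The fit was kept as it had been fixed, and in these simulations its share of false calls was above the nominal 5 in 100.

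Alternatives covered 4 other scalings (quantile, as deposited, by hybridisation spikes, by the 75th percentile), other offsets, filters and floors, other prior variances, a 2-fold requirement, 1 probe set per gene, a 5-fold rule and each pollen array left out. Floors at the highest control probe set without a spiked target were added after the data were seen. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.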

Results

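Germinating pollen with pollen tubes was compared with whole seedlings, roots included, to find the genes whose transcripts dominate in germinating pollen. A pollen tube is the cell that grows out of the pollen grain and carries the sperm cells to the ovule. The data are 2 germinating pollen arrays and 1 seedling array. At the floor of 42.3, 47.8% and 50.2% of probe sets were above it on pollen arrays 1 and 2, against 52.0% on the seedling array. The floor is the pooled median of the same arrays, so the average of these shares was fixed by construction. Controls without a target reached 47.1 and 65.7 on the pollen arrays and 14.3 on the seedling array. The shares therefore do not compare how many transcripts were detected in each tissue. The brightest 455 probe sets held 65.6% and 65.2% of the summed signal on the pollen arrays and 34.5% on the seedling array. Across the 22746 probe sets, which are not independent replicates, the pollen arrays correlated with each other at r = 0.906 (Spearman 0.769) on the log2 scale, and each correlated with the seedling array at r = 0.176. The SD between the pollen arrays was 0.30 log2 units among the brightest 7582 probe sets by pollen signal, 0.77 among the middle 7582 and 0.48 among the dimmest 7582.

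Germinating pollen and seedlings differed in a large part of the measured transcripts. By size alone, 965 probe sets were at least 10-fold higher in germinating pollen on both arrays, and 1127 were at least 10-fold lower. Scaled by the hybridisation spikes, the same rule gave 560 higher and 4185 lower. That scaling shifted log2 differences by -2.31 in comparison with the trimmed mean, so the folds given for genes higher in pollen are smaller under it. The 965 held 72.1% and 71.5% of the summed signal of the pollen arrays but 1.2% of that of the seedling array. The rule chose them on these same arrays for being at least 10-fold higher in pollen, so this contrast follows in part from the rule. For 653 of the 965 the seedling signal was at or under the floor. Of the 965, 555 had exactly 1 gene in the annotation, as did 454 of the 1127. With limma and Benjamini-Hochberg adjustment, 3281 of 14815 tested probe sets were higher in germinating pollen and 4691 were lower, so that 41.2% of the calls were higher. That split was 48.2% with quantile normalisation (3585 higher, 3858 lower), 53.1% when arrays were scaled by their 75th percentile (4318 higher, 3807 lower) and 10.7% when scaled by the hybridisation spikes (1423 higher, 11862 lower). In simulated data 89 of 96 false calls were of lower signal in pollen, but every simulated array was drawn from the pollen signals. The higher background of the pollen arrays was not simulated, so these counts do not tell how false calls divide in the data. Under spike scaling 1423 of the 3281 higher calls were made again and 336 turned to lower.

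**Figure D1:**
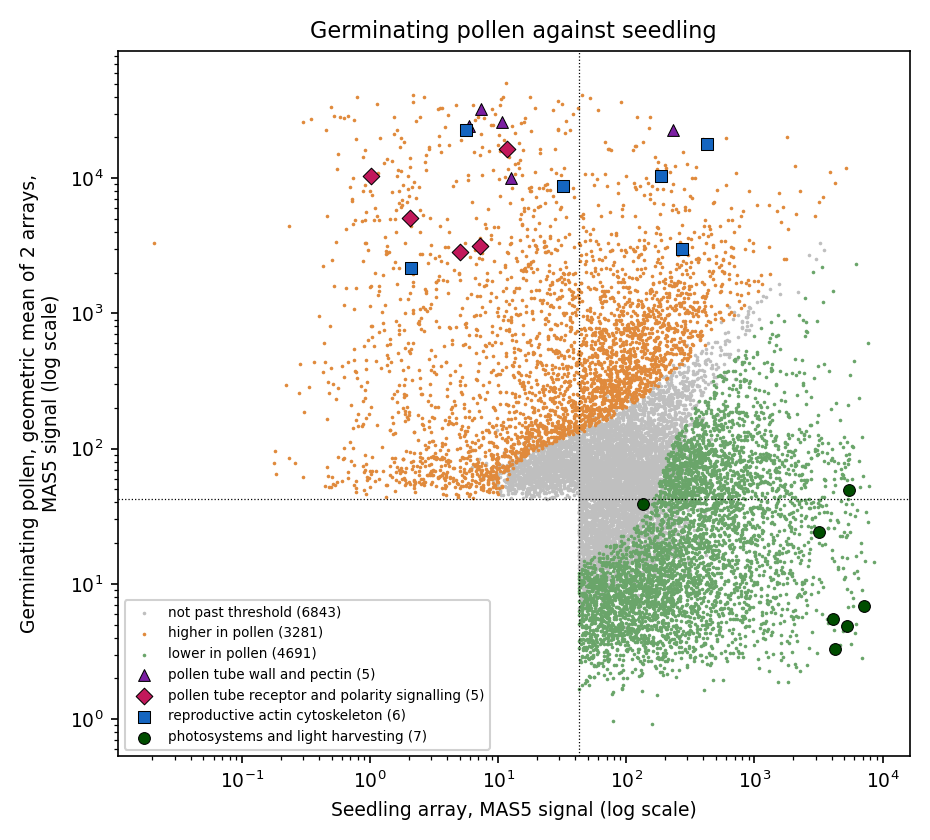
Geometric mean signal of the 2 germinating pollen arrays (vertical, MAS5 signal, log scale) against the signal of the seedling array (horizontal, MAS5 signal, log scale) for the 14815 tested probe sets, where 1 point is 1 probe set, colours give the limma call, large symbols are members of 4 gene lists and dotted lines mark the floor of 42.3. The wall, receptor and reproductive cytoskeleton genes lie at high pollen signal, and the photosystem genes lie at high seedling signal, with LHCB4.3 nearest to the rest.

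The 8 genes with the highest pollen mean among those called with the seedling signal at or under the floor were at least 823-fold to 1197-fold higher. AT3G07820, a polygalacturonase, had a mean pollen signal of 40866 ± 534 (SD, n = 2) against 2.18 in seedlings, at least 966-fold higher. AT5G07430, a pectin methylesterase, reached 39528 ± 1763 and was at least 934-fold higher. AT3G01270, a pectate lyase, reached 38398 ± 217 and was at least 907-fold higher. The highest pollen mean of all such genes belonged to AT3G28750, at 50646 ± 462 and at least 1197-fold. AT3G26110, AT2G47050, AT1G78460 and AT1G10770 were at least 940-fold, 867-fold, 841-fold and 823-fold higher. The seedling signals of all 8 genes came from 1 array at or under the floor, so their spread is unknown and no p-value is given. Among genes above the floor on all 3 arrays, AT5G19580 showed the largest difference, 753-fold (log2 difference 9.20). Its seedling signal of 52.3 came from 1 array and lay close to the floor, so no SE or p-value is given. AT3G59350 was 201-fold higher, AT4G25780 185-fold, SOL1 160-fold, SGP2 157-fold (its pollen signals were 12931 and 8958) and SP1L4 145-fold.

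Cell wall genes fixed beforehand as pollen tube genes were higher without exception among the 5 measured, of 25 in the list. LRX8, LRX9, LRX10 and LRX11 encode leucine-rich repeat extensins, cell wall proteins of the pollen tube. LRX9 had a pollen signal of 32295 ± 651 (SD, n = 2) against 7.39 in seedlings, at least 763-fold higher, LRX10 was at least 619-fold, LRX8 at least 577-fold and LRX11 at least 235-fold higher. EXPA4, an expansin, was 98.1-fold higher. The list's median log2 difference was 10.01, above 99.96% of random lists. With signals under the floor raised to it, the median was 9.17. Camera gave an adjusted p = 1.2e-05 with the preset correlation, and adjusted p = 0.396 with an estimated correlation. All 5 also passed when adjusted over the list alone.

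Receptor genes of the pollen tube surface were higher in 5 of 5 measured members of a list of 37. These were the receptor kinases ANX1, ANX2, BUPS1 and BUPS2, which maintain the integrity of the growing tube, and MRI, a cytoplasmic kinase acting with them. BUPS1 was at least 387-fold higher (pollen 16548 ± 3321, SD, n = 2, seedling 11.7), ANX2 at least 247-fold, ANX1 at least 121-fold, BUPS2 at least 73.9-fold and MRI at least 67.3-fold. The median log2 difference was 8.25, or 6.92 with signals raised to the floor, above 98.3% of random lists (camera adjusted p = 3.1e-05; adjusted p = 0.388 with an estimated correlation). All 5 passed adjusted over the list alone.

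Cytoskeleton genes of reproductive tissue were higher in pollen. The measured ones of vegetative tissue, all of them tubulin or LIM protein genes, went both ways. The actins ACT2, ACT7 and ACT8 of the vegetative list, and its profilin and ADF genes, were not measured. The array's actin control, whose gene is not named here, had 3' signals of 51.9 and 10.4 in pollen against 1723 in seedlings. All 6 measured genes of the reproductive list of 25 were higher. PLIM2a and PLIM2b, actin-bundling LIM proteins of pollen, were at least 531-fold and at least 206-fold higher. ACT12 was at least 51.2-fold and ACT11 11.1-fold higher, both being actins of reproductive tissue. The tubulins TUA1 and TUB9 were 55.8-fold and 42.1-fold higher. The list's median log2 difference was 6.36, or 5.74 with signals raised to the floor, above 92.9% of random lists (camera adjusted p = 1.2e-05; adjusted p = 0.388 with an estimated correlation), and 6 of 6 passed adjusted over the list alone. Of 8 measured genes in the vegetative list of 31, 4 were higher and 3 lower, while TUB6 did not pass (pollen 9.92 and 93.9, seedling 387). TUB1 was 20.9-fold and WLIM2a 13.8-fold higher. Against the floor, TUB5 was at least 9.35-fold and WLIM1 at least 4.32-fold lower, and WLIM2b was 2.61-fold lower than in seedlings. TUA6 was 2.98-fold and TUB7 2.02-fold higher, and under spike scaling both turned to lower. The vegetative list's median and mean log2 differences were -0.18 and -0.13, and its median was above only 4.78% of random lists, whose median was 1.75, while camera gave the direction up without passing (adjusted p = 0.507). Adjusted over the list alone, 4 were higher and 4 lower.

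Transcription factors of pollen were higher in 7 of 8 tested members, with 9 of 14 measured. AGL30, AGL65, AGL66 and AGL104 are MADS-domain factors that act in pollen maturation and tube growth. AGL104 had a pollen signal of 1757 ± 142 (SD, n = 2) against 5.02 and was at least 41.4-fold higher. BZIP18 was 50.1-fold and AGL66 at least 22.7-fold higher, AGL65 21.1-fold, AGL30 at least 20.6-fold, AGL29 at least 6.01-fold and BZIP34 at least 3.98-fold higher. BZIP52 did not pass (117 and 93.8 in pollen, 61.9 in seedlings), and AGL94 was not tested. The median log2 difference was 4.28, or 4.39 with signals raised to the floor, above 99.86% of random lists (camera adjusted p = 7.2e-05; adjusted p = 0.388 with an estimated correlation). The same number, 7, passed adjusted over the list alone.

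In the list of DNA replication and mitosis, 3 of 4 measured members were higher, out of 43 listed. AUR2 and AUR1, Aurora kinases that act on chromosomes at mitosis, were 38.1-fold and 15.5-fold higher, with pollen signals of 2950 ± 436 and 2155 ± 27.9 (SD, n = 2). MCM7, a part of the replicative helicase, was 5.18-fold higher, but its log2 difference fell from 2.28 to 0.06 under spike scaling and was no longer called. AUR2 went from 5.01 to 2.87 and AUR1 from 3.82 to 1.61 there. BUB3.1 did not pass (39.6 and 88.3 in pollen, 83.2 in seedlings). The list passed camera (adjusted p = 0.0143; adjusted p = 0.388 with an estimated correlation), while its median log2 difference of 3.05, or 3.16 with signals raised to the floor, was above only 60.2% of random lists and was 0.84 under spike scaling. Adjusted over the list alone, 3 passed.

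Photosynthesis genes were far lower in germinating pollen. Of 7 measured photosystem and light-harvesting genes in a list of 33, 6 were lower, and LHCB4.3 did not pass (34.4 and 43.7 in pollen, 135 in seedlings), while 7 were lower adjusted over the list alone. LHCB4.1, an antenna protein of photosystem II, had a seedling signal of 7216 against 7.73 ± 4.95 (SD, n = 2) and was at least 171-fold lower. LHCB4.2 and PSBW were at least 124-fold and at least 101-fold lower. The bounds of LHCB4.1, LHCB4.2 and PSBW hold against the floor only, since their pollen signals were under the highest control without a target. The list's median log2 difference was -7.66, or -6.64 with signals raised to the floor, below all 10000 random lists (camera adjusted p = 0.00107; adjusted p = 0.388 with an estimated correlation). All 7 measured genes of the Calvin cycle and chlorophyll synthesis list of 29 were lower, 7 also adjusted over the list alone. PRK, phosphoribulokinase, was 69.9-fold lower (log2 difference -5.88), with pollen signals of 69.1 and 85.5 against 5377 in seedlings. Its pollen signals were above the highest control without a target on both arrays (47.1 and 65.7), but near it, so the fold is uncertain. No SE is given, since the seedling signal came from 1 array. RCA, the activase of Rubisco, had a seedling signal of 6818 and pollen signals of 3.81 and 76.8, and SBPASE had 4405 against 86.4 and 10.1, so that the pollen arrays disagreed on both. This list's median was -4.94, or -5.03 with signals raised to the floor, also below all 10000 random lists (camera adjusted p = 0.00382; adjusted p = 0.388 with an estimated correlation).

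Among other genes lower in pollen, PSAE-1 of photosystem I was at least 144-fold lower, and AT2G45180, AT5G20290, AT1G09310, AT4G01150 and AT2G26500 were at least 119-fold, 116-fold, 110-fold, 110-fold and 107-fold lower. AT4G01150 is CURT1A, a thylakoid membrane protein. A further 5 genes were called lower with all 3 arrays above the floor, but each was under the highest control without a target (47.1 on pollen array 1, 65.7 on array 2) on 1 pollen array, so their signals are given without folds. The plastid gene psbM had 61.3 and 59.9 in pollen against 5040 in seedlings, and ATPC1, a subunit of the chloroplast ATP synthase, had 83.2 and 44.8 against 4757. HPR had 45.6 and 89.0 against 4875, AT1G74470 had 54.5 and 52.7 against 4241, and AT1G51400 had 55.7 and 63.5 against 4162.

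**Figure D2:**
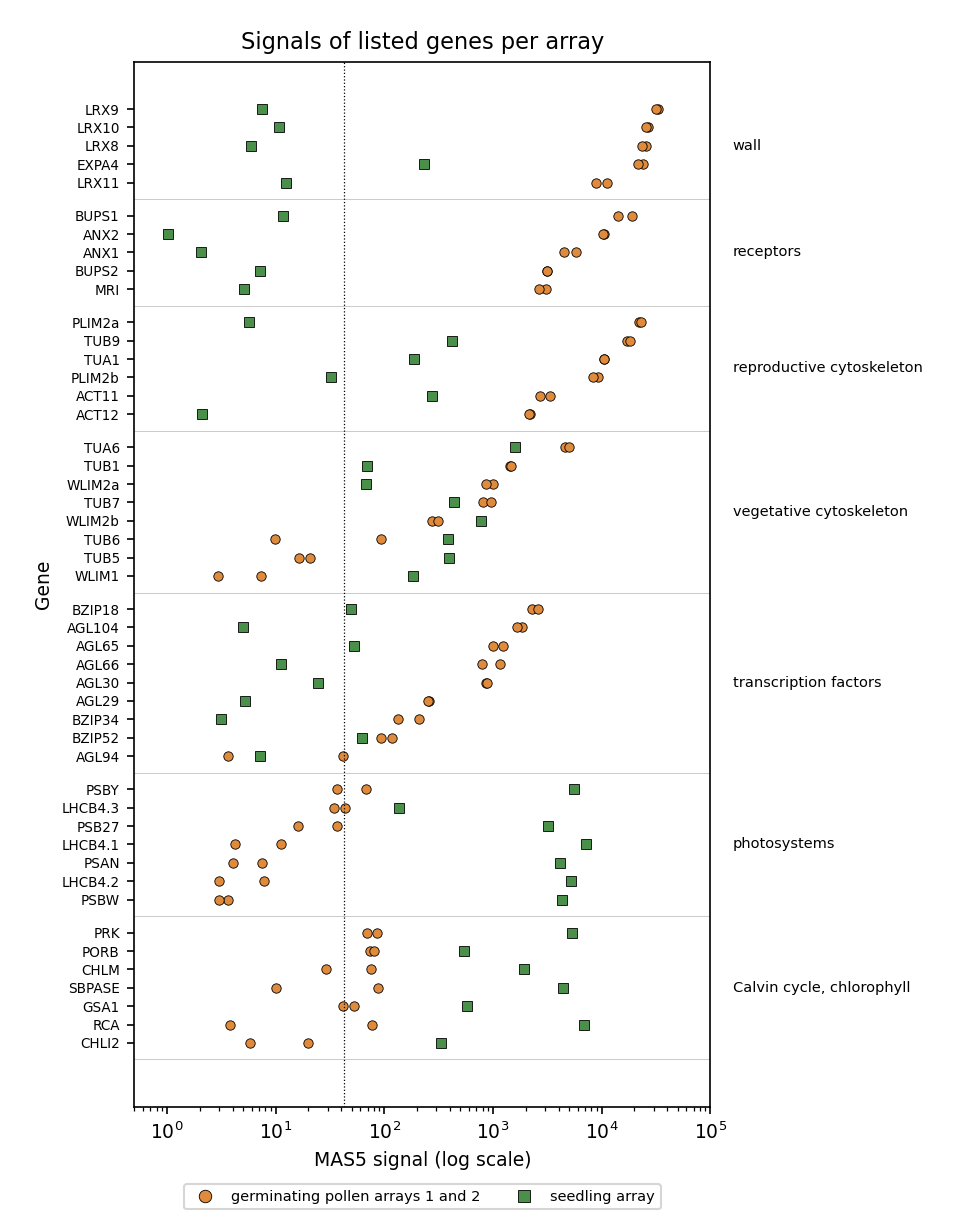
MAS5 signal (horizontal, log scale) of each measured gene (vertical) of 7 gene lists, with circles for the germinating pollen arrays and squares for the seedling array, and the floor of 42.3 as a dotted line. Wall, receptor and reproductive cytoskeleton genes have both circles to the right of the square, whereas photosystem and Calvin cycle genes have both circles to its left; the pollen arrays lie apart for dim genes such as RCA (3.81 and 76.8).

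Few genes of tissues that could have come along with the pollen were measured. The tapetum is the anther layer that surrounds developing pollen, and its genes A9 and AMS did not reach the floor on both pollen arrays (A9 14.8 and 39.1, AMS 8.88 and 49.0), so they were not tested. Of 6 measured genes of petals, stigma and other flower organs, 4 were tested, and 0 were higher. NGA1 was lower, by at least 2.07-fold against the floor. Adjusted over the list alone, 1 was lower. SPT, RBE and NGA2 did not pass, with mean pollen signals of 118, 72.9 and 104 against 39.6, 11.3 and 56.2 in seedlings. The list did not pass camera (adjusted p = 0.578), but its median log2 difference of 1.02 was above 96.6% of random lists, whose median was -0.90; its mean was 0.33, and its median was -0.95 under spike scaling. Of the seedling's root markers, EXPA7 was higher in pollen by at least 2.61-fold (limma adjusted p = 0.0415), although its log2 difference was 0.01 under spike scaling and no longer called, and EXPA18 did not pass (113 and 56.4 against 23.6).

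The remaining lists had few measured genes. CHX21, a cation/proton exchanger, was at least 9.80-fold higher. ROF2, an immunophilin of the heat stress response, was at least 32.3-fold higher, and PDC2, a pyruvate decarboxylase, was called lower with pollen signals of 8.87 and 6.33 against 46.5, a seedling signal close to the floor; the call was lost without the offset (log2 difference -2.63), and the gene did not enter the test under quantile normalisation or 75th percentile scaling. SEC6 (109 and 108 against 185), DME (67.5 and 61.0 against 32.8) and SE (26.7 and 10.9 against 59.9) did not pass. IAA34 was called higher with a pollen mean of 51.4, below the highest signal of a control probe set without a target (65.7); the call was lost under quantile normalisation and without the offset, and under spike scaling the gene did not enter the test (log2 difference 0.03). Of the auxin list, 0 of the 3 tested auxin genes passed adjusted over the list alone. That list did not pass camera (adjusted p = 0.865); its median log2 difference was -0.23 and its mean 0.03.

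Of 17 reference genes 2 were measured, and 1 was lower in pollen. GAPC2, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, had a seedling signal of 5327 against 46.4 and 38.6 in pollen (limma adjusted p = 0.00013), where both signals were under the highest control without a target on their array (47.1 and 65.7), so no fold is given. UBC21 did not pass (118 and 22.1 against 251; limma adjusted p = 0.135), but passed under spike scaling with a log2 difference of -4.02. The 9 hybridisation spike probe sets were on average 5.25-fold and 4.69-fold brighter on the pollen arrays than on the seedling array. The 3' to 5' signal ratio of the ubiquitin control, a measure of RNA integrity and labelling, was 2.02 and 2.42 in pollen and 1.59 in seedlings, and in an older ubiquitin control 4.86 and 6.08 against 2.85. No ratio is given for the GAPDH and actin controls, whose 5' signals in pollen (44.0 and 27.0 for GAPDH, 9.11 and 21.6 for actin) were under the highest control without a target on their array.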

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

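The floors at control probe sets without a target were chosen after the data were seen, and the other alternatives before. Of the 7972 calls, spike scaling gave 13285 (1423 higher, 11862 lower), where the median log2 difference of all tested probe sets was -2.27 against -0.60, and 336 of the 3281 higher calls became lower. The cause was not tested beyond the controls described under other observations. With 1 probe set per gene there were 4085 calls (1883 higher, 2202 lower), because only 8096 were tested. Quantile normalisation moved that median to -0.26 and 75th percentile scaling to 0.02. No filter gave 2627 higher and 3161 lower, no offset 3080 and 3366, and a floor per array at the highest control without a target 2867 and 4517. By the 10-fold rule, 965 higher and 1127 lower became 560 and 4185 under spike scaling, 1994 and 2288 with no floor, 1526 and 2161 at 5-fold, and 1798 lower with the floor at the 30th percentile; looser rules take more by construction. A floor at the highest control without a target on any array gave 847 and 877. Leaving out either pollen array gave 998 to 1018 higher and 1201 to 1231 lower, with no test. The 7 gene lists past the threshold became 0 when the correlation was estimated. There 1 residual degree of freedom leaves little to estimate it from. Every other setting run gave 7. Camera compares a list with the other probe sets, so scaling by 1 factor per array can hardly move that count. Of 60 named genes tested, TUA6 reversed under spike scaling (-0.74). MCM7 (0.06) and EXPA7 (0.01) lost their calls there, IAA34 lost its call under quantile normalisation (1.54) and no offset (2.35), PDC2 under no offset (-2.63), and UBC21 gained one under spike scaling (-4.02). By the filter, IAA34 was not tested under spike scaling (0.03), nor PDC2 under quantile normalisation (-1.35) or 75th percentile scaling (-1.11). No paired analysis was possible because the seedling array carries no replicate number and has no second array. Signal over background limits dim probe sets: controls without a target reached 47.1 and 65.7 on the pollen arrays and 14.3 on the seedling array.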

Other observations

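All tests of explanations in this part were chosen after the results were seen. The families here were picked from the symbols of the annotation and are not independent of it. Genes of the plastid genome were lower in 59 of 66 tested members and higher in 0, with a median log2 difference of -5.06, or -4.60 with signals raised to the floor (limma's camera adjusted p = 1.9e-11 over 22 families; adjusted p = 0.804 with an estimated correlation). The gene psbH of photosystem II had a seedling signal of 3077 against 5.29 and 1.77 in pollen, at least 72.7-fold lower against the floor. CHX cation/proton exchangers were higher in 4 of 4 tested members, of 6 measured. CHX15 was at least 57.7-fold, CHX19 at least 35.2-fold and CHX6B at least 28.1-fold higher, beside CHX21. Camera gave an adjusted p = 0.00319, and adjusted p = 0.804 with an estimated correlation. The highest seedling signal of the 6 was 31.5, under the floor. A member was thus tested only if above the floor on both pollen arrays, and none could have been called lower. The count of 4 and the camera result rest on members admitted for their pollen signal, so they cannot decide the direction of the family. A further 19 families did not pass.

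Several families that did not pass held members far apart. RALF-like genes encode small secreted signalling peptides, and RALFL26 and RALFL25 were at least 586-fold and at least 227-fold higher, while RALFL33 was at least 10.5-fold lower; the family's median log2 difference was -1.85 and its mean 0.50 (camera adjusted p = 0.918). Among cell wall hydrolases, GH9A4 and GH9B11 were at least 702-fold and at least 237-fold higher, and GH9B7 was at least 18.3-fold lower (adjusted p = 0.376). NET2C and NET2D, actin-binding proteins, were at least 35.8-fold and at least 9.85-fold higher, while NET1A, NET1D and NET3A were called lower (adjusted p = 0.918). Of 11 tested tetraspanins 5 were higher and 2, TET2 and TET3, lower (adjusted p = 0.169); TET13 was at least 67.9-fold and TET16 at least 15.4-fold higher, and TET7 and TET8 turned to lower under spike scaling. Of the families with corrected symbol patterns, CYP71 cytochromes P450 had 0 higher and 2 lower of 8 tested (adjusted p = 0.403), and IQD calmodulin-binding genes had 1 higher and 4 lower of 9 (adjusted p = 0.376).

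The hybridisation spikes were 5.25-fold and 4.69-fold brighter on the pollen arrays. More spike in the pollen hybridisations would leave control probe sets without a target at their level, but these were also brighter, by a median of 4.35-fold (bootstrap 95% interval 3.54 to 6.42 over 27 probe sets), and 25 of 27 were higher on both pollen arrays, which argues against it. The same value of 4.35 is consistent with the scaling of each array to a common trimmed mean. Dominant transcripts left out of the trimmed mean are not the whole cause, since the untrimmed mean relative to the spikes was still only 0.364 and 0.402 of the seedling value. A lower amount of labelled RNA on the pollen arrays, and a tissue difference in messenger RNA content, stay open and untested.

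Calls higher in pollen could come from the raised background of the pollen arrays. Of the 3281 calls, 171 (5.21%) had a mean pollen signal at or under the highest control without a target, 65.7. The filter kept only probe sets above the floor of 42.3 on both pollen arrays or on the seedling array. A call of higher signal could thus hardly have a pollen signal under the floor, which kept this share low. The share therefore cannot decide on background, which stays open as a cause of the calls. A difference between the tissues also stays open as a cause of the 3281 calls and was not tested separately from background.

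The low GAPDH signal in pollen was also seen in the array's GAPDH control probe sets. Loss of the 5' part of the RNA would spare the 3' probe set, but that probe set was 18.5-fold lower on pollen array 1 and at least 22.3-fold lower on array 2, where its signal was raised to the highest control without a target. The log2 difference of GAPC2, with pollen signals raised to that control, was -5.99 or lower under each of the 5 scalings. The test was chosen after the results, and spike scaling shifted log2 differences by only -2.31, so it could hardly have come out otherwise. It shows only that none of the 5 scalings removed the difference. Use of another isoform in pollen may explain the low signal and was not tested.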
